A study of Mus musculus with 10 samples.

How the data were processed

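Gene expression was measured on Illumina mouse bead arrays with 1 colour (Cy3), 1 array per RNA sample, in 10 samples. Per the labels, 8 samples came from 3 lines of induced pluripotent stem (iPS) cells named KU-iN1 (n = 2), KU-iN2 (n = 3) and KU-iN3 (n = 3), and 2 came from J1, an established male mouse embryonic stem (ES) cell line. The iPS lines were made from mouse embryonic fibroblasts with plasmids that carry Oct4, Sox2, Klf4 and c-Myc, brought into the cells with magnetic nanoparticles, and each colony was then grown on STO feeder cells, a fibroblast line. Total RNA was extracted with a Qiagen column kit, per the labels' protocols. Fibroblasts were not analysed here. The labels number the samples of a group as biological replicates without saying that they came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

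The authors deposited 2 kinds of values for the 46643 probes. The first is a table of raw probe intensity on a linear scale, per the file headers a signal for each probe and sample. It gives neither detection p-values nor control probes and holds 1537 empty lines. The second is the deposited series matrix, whose values are on a log2 scale. Its own header names no scale or normalization, so each of its columns was set against the raw intensity of the same array: quantile normalization of log2 intensity gave its values to within 0.0264, with a median difference of 0.000411. Its columns have medians of 7.588 to 7.591 and are not centred on 0. The submitters' processing notes name R 2.9.1, and the background correction and the scanner software settings are not given in the sources used here.

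The raw intensities were background-corrected by the normexp method with an offset of 50, taken to log2 and quantile normalized between arrays with limma 3.58.1 in R 4.3.3 (with the data.table package, version 1.17.8). This was the setting fixed for a raw table without detection p-values or control probes, in place of the neqc method that such values would have allowed. A detection value was built in their place from 1303 probes for olfactory and vomeronasal receptors, genes that stem cells are not known to use. For each probe it is the share of these receptor probes on the same array with a signal at least as high. Probes with a value under 0.01 on at least 2 arrays were kept, which left 12804 probes, 18 of them receptor probes. A probe is called detected on an array where this value is under 0.01. Where a gene was not detected on any array of a group, its difference is given as "at least N-fold": the mean of the brighter group over all its arrays is set against the mean of, per array, the higher of the lowest signal among detected probes and the dim probe's own signal.

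Probe names came from the platform annotation that was provided with the data, which can be old. Of the probes, 32794 have 1 gene symbol, 55 have several and 13794 have none. Of the named probes, 32722 matched the mouse GRCm38.p6 gene table by gene identifier, with 0 symbols changed. Probes with several symbols or none were tested but are not named. The probe with the highest mean log2 value over the 10 arrays stood for its gene where a gene had several kept probes, as for 2052 genes. This gave 10159 features, of which 8156 are named genes and 2003 unnamed probes. Positions of the probe sequences within transcripts were not used here, and no coordinates are printed. The gene table served only to place genes on chromosomes and in gene order.

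A linear model with a mean for each of the 4 groups was fitted to all 10 arrays (limma lmFit and eBayes, 6 residual and 8.44 prior degrees of freedom), so that the small groups shared one estimate of the spread. The 7 comparisons were the equal-weight mean of the 3 iPS lines against J1, each line against J1, and each pair of lines. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all features tested, and every adjusted p of a gene is from this limma fit. A log2 difference is given with its standard error (SE), as first group minus second. Gene lists were tested with camera at a preset correlation of 0.01 and again with a correlation estimated for each list, adjusted over the lists of a comparison, for lists with at least 3 measured members. The 24 lists cover pluripotency, lineage markers, feeder and fibroblast markers, imprinting, signalling, metabolism, stress and control genes.

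Fixed before the data were examined were the groups, the test, the lists, the alternatives other than the 3 named as added, and the rule for named genes. By that rule the text may name the 10 largest rises and falls of the iPS lines against J1 and the 5 largest rises and falls of each other comparison, among called genes whose groups did not overlap. It may also name a set of stem cell, imprinted, sex-linked and fibroblast genes whatever their result, and per list up to 4 members with the smallest adjusted p in the iPS lines against J1 and up to 2 in a comparison of lines. Other genes named in the text were chosen after their values were seen.

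The test was tried on simulated data with known changes in the means and spreads of these arrays. For the iPS lines against J1 (9475 genes), 31.3% of genes changed by 0.5 on the log2 scale were found, 91.0% of those changed by 1 and 100% of those changed by 2, with 9 false calls among 157. For KU-iN2 against KU-iN3 (9338 genes) the shares were 35.8%, 85.1% and 100%, with 2 false calls among 149. Changes were given to only 66 or 67 tested genes of each size, all with a probe above a mean raw log2 signal of 9. The shares therefore do not cover dim genes. Nor do they carry over to the real comparison with J1, where far more features were called. The number of arrays limits the precision of all values.

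Alternatives were no background correction, cyclic loess, median centring, the series matrix values, no detection filter, detection on all 10 arrays, the mean of a gene's probes, each probe on its own, a trended and robust variance model, array weights, the replicate number as a block, fits of only the groups compared, stricter thresholds, line means as replicates, an estimated list correlation, and each array left out in turn. Added after seeing the data were neqc with the receptor probes as negative controls, quantile normalization within each of the 2 blocks of probe numbers (24613 and 22030 probes), and a fit without the genes of chromosomes 1, 8 and 14. Neither file says which chip held which sample, so a chip effect could not be modelled.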

Results

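Expression profiles of 3 mouse iPS cell lines, made from fibroblasts without viruses by nanoparticle delivery of Oct4, Sox2, Klf4 and c-Myc plasmids, were compared with those of the ES cell line J1. The comparison asks how close the reprogrammed lines are to this ES line and to each other. J1 is the only ES line, so the spread between ES lines is not measured. A difference from J1 can be a trait of that line, of its culture or of a batch, and these cannot be told apart. There were 2 arrays of KU-iN1, 3 of KU-iN2, 3 of KU-iN3 and 2 of J1. Median raw intensity was 176 to 206 per array, near the median of the receptor probes that stood for background (171 to 196), and the 90th percentile was 807 to 1013. Between 10542 and 12208 probes (22.6% to 26.2%) were detected per array. The standard deviation of the log2 difference between replicates over genes was 0.180 to 0.266.

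Arrays of one iPS line resembled those of the other lines far more than those of J1. Pearson's r across genes averaged 0.993 between arrays of one group, 0.987 between arrays of different iPS lines and 0.933 between iPS and J1 arrays. The difference of the last pair of values was -0.0540 (exact permutation test over the 45 ways of choosing 2 of 10 arrays, two-sided p = 0.0222, the smallest this design allows). Arrays of one line are not exchangeable with those of another and genes are not independent replicates, so this p is a description. On the axis of largest variance, which held 68.0% of the variance, the J1 arrays lay at 50.6 and 49.5 and the iPS arrays at -11.6 to -13.5. The next axis, with 11.9%, placed KU-iN3 at -10.3 to -16.1, KU-iN1 at 0.360 and 4.19, and KU-iN2 at 11.1 to 14.2.

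**Figure D1:**
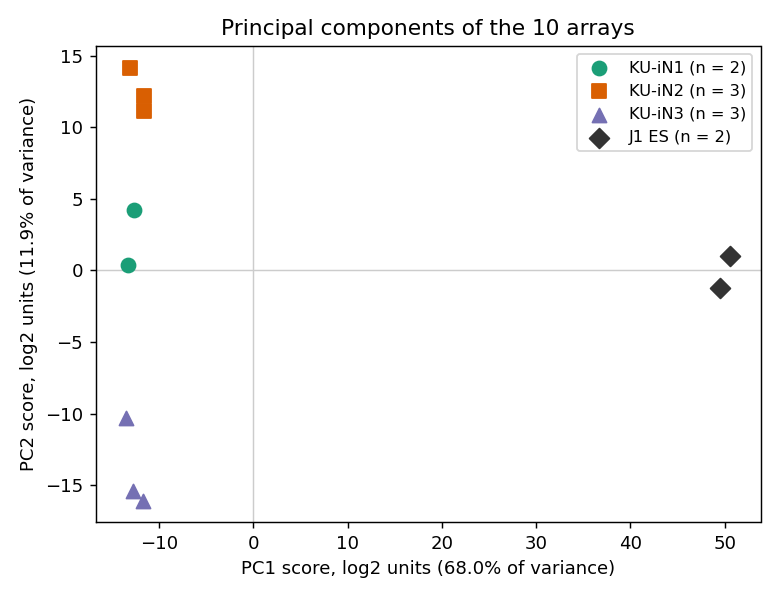
Position of the 10 arrays on the axes of largest and second largest variance (arbitrary log2 units) of the genes tested, coloured by line. The J1 arrays sit at 50.6 and 49.5 on the horizontal axis and all iPS arrays between -11.6 and -13.5.

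Against J1, the 3 iPS lines had much lower signal for replication-dependent histone genes and higher signal for single genes such as Trh, Lefty2 and Egr1. Trh, the precursor of thyrotropin-releasing hormone, rose by 3.55 on the log2 scale (SE 0.11, n = 8 against 2, adjusted p = 1.67e-12), with a mean of 10.2 ± 0.13 (SD, n = 2) in J1 and 13.8 ± 0.17 (n = 3) in KU-iN3. Lefty2 and Lefty1, secreted inhibitors of Nodal signalling, rose by 3.32 (SE 0.09) and 2.65 (SE 0.10). Gsta3, a glutathione transferase, rose by 3.33 (SE 0.10), and the immediate early transcription factors Egr1 and Fos by 3.10 (SE 0.09) and 2.70 (SE 0.18). The histone H4 gene H4c18 fell by 6.69 (SE 0.11, adjusted p = 2.34e-15), and H4c12 fell by 6.46 (SE 0.09, adjusted p = 5.01e-16).

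In total 5788 of 10159 features were called (57.0%), 2980 higher and 2808 lower in the iPS lines, and 742 of them differed at least 2-fold (320 higher, 422 lower). The balance of 51.5% higher turned under some alternatives. It was 44.0% with cyclic loess, 47.4% with median centring, 49.3% with no detection filter and 46.9% without chromosomes 1, 8 and 14. Among named genes 4647 were called, 2538 higher and 2109 lower. In 4790 of the called features the iPS and J1 arrays did not overlap. Without J1 replicate 1 the count was 4513. With the 3 line means as the replicates, so that the spread between the iPS lines alone was the error, it was 3491. The other large rises were Stmn2, a neuronal microtubule regulator (2.84, SE 0.14), S100a6 (2.78, SE 0.16), Nxn (2.53, SE 0.10) and Fmr1nb, which was not detected in J1 and was at least 5.90-fold higher. Stmn2 and Fos were each detected on 1 of 2 J1 arrays. The 10 largest falls were all histone H4 or H3 genes, from H3c4 (-5.03, SE 0.12) to H4c18. Their sequences are near-identical copies, so the signal of one cannot be assigned to that gene with certainty.

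The pluripotency network differed little as a group. Of 33 members tested 8 rose and 5 fell (8 and 4 adjusted over the list alone), with a median of 0.01 and no shift by camera (adjusted p = 0.658). Pou5f1, the gene of Oct4, differed by 0.05 (SE 0.11, adjusted p = 0.682), Sox2 by 0.14 (SE 0.10, adjusted p = 0.223), Nanog by -0.21 (SE 0.13, adjusted p = 0.176) and Zfp42, the gene of Rex1, by 0.02 (SE 0.15, adjusted p = 0.927). For Pou5f1 and Zfp42 the sign turned under several alternatives, as with cyclic loess (-0.02 and -0.05), and the other Pou5f1 probe had the opposite sign. Gbx2, a homeobox factor, rose by 1.76 (SE 0.10) on its brighter probe, while its other probe had the opposite sign. Tcl1, a co-activator of Akt, rose by 0.96 (SE 0.11), Tex19.1 by 0.91 (SE 0.09), and Jam2, a cell adhesion molecule, fell by 1.26 (SE 0.10). Among the 4 transfected factors, 1 rose and 1 fell (camera adjusted p = 0.827): Klf4 fell by 0.59 (SE 0.12, adjusted p = 0.000784) on the log2 scale, and Myc, not detected in J1 and detected on 6 of 8 iPS arrays, was at least 1.29-fold higher (adjusted p = 4.39e-05). With line means as the replicates the adjusted p of Klf4 was 0.05004. Whether the probes of these genes read plasmid as well as chromosomal transcripts was not determined.

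**Figure D2:**
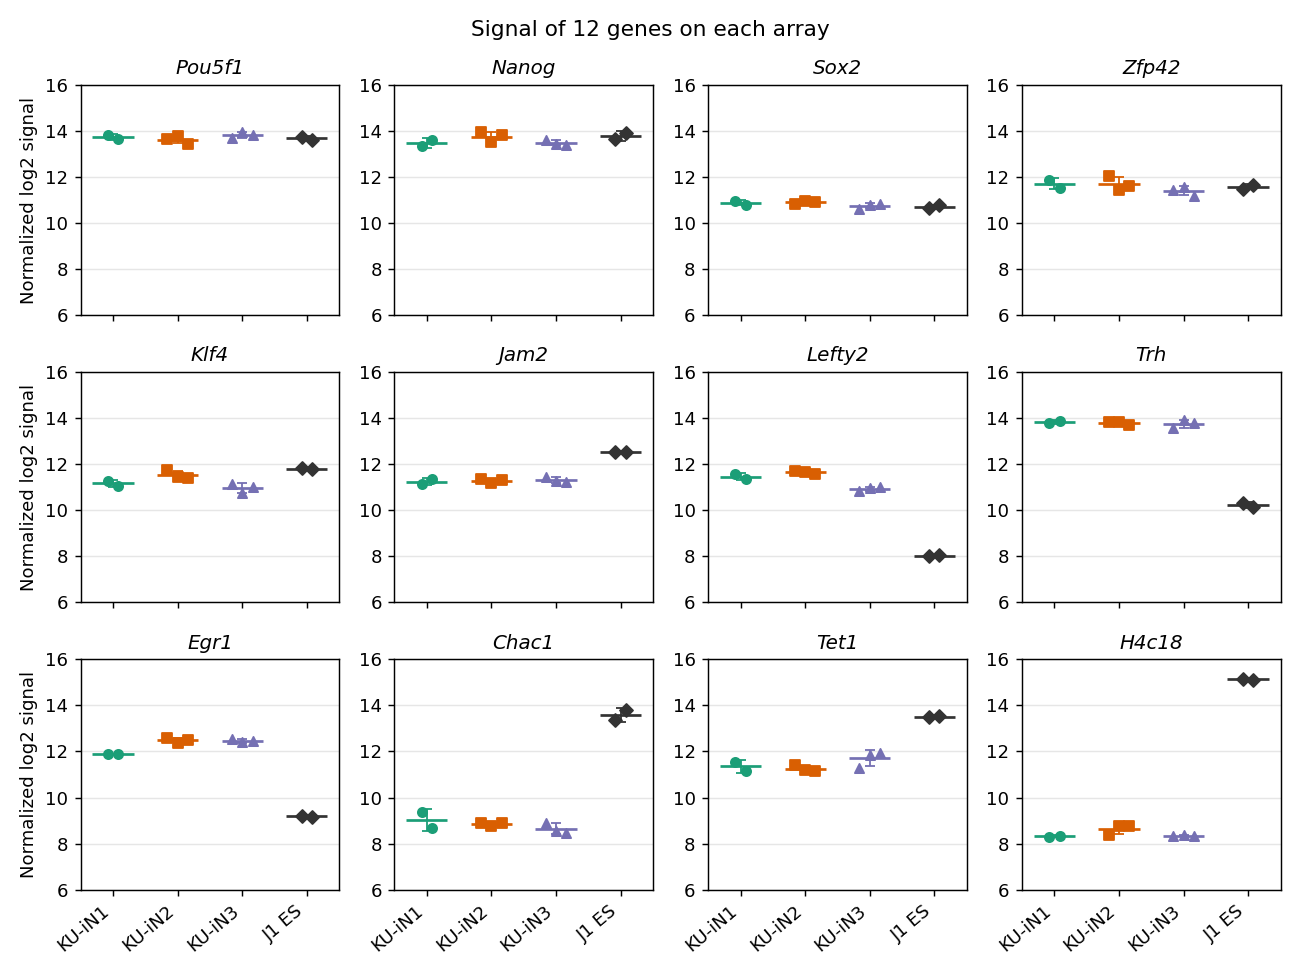
Normalized log2 intensity of 12 genes on each of the 10 arrays by line, with a line at each group mean and bars of 1 SD. Pou5f1 lies near 13.7 in all 4 groups, while Trh is at 10.2 in J1 and 13.8 in the iPS lines and H4c18 at 15.1 in J1 and 8.3 to 8.6 in the iPS lines.

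Markers of fibroblasts and feeder cells were the 1 list of 22 tested that camera called. Of its 16 members tested 9 rose and 1 fell, with a median of 0.35 (adjusted p = 0.0326). The call was lost with an estimated correlation (adjusted p = 0.348) and with median centring (adjusted p = 0.0620). S100a6, Tgfbi, Ccn2 and Vim, a calcium-binding protein, a matrix protein, a matricellular growth regulator and the mesenchymal filament vimentin, rose by 2.78, 1.46 (SE 0.11), 1.40 (SE 0.16) and 1.22 (SE 0.10). Thy1, a fibroblast surface marker, rose by 0.84 (SE 0.13). The probe of Col1a1, the main collagen of fibroblasts, was not detected on any array.

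Lineage markers moved in both directions, and none of these lists was called. In primed epiblast 3 of 7 tested rose and 1 fell (adjusted p = 0.534), among them Pou3f1, a POU-domain factor of the epiblast (1.60, SE 0.11), Dnmt3b (0.78, SE 0.11) and Nodal (-1.10, SE 0.10). In the endoderm list 8 of 13 rose and 3 fell (adjusted p = 0.534): Rhox5 was not detected in J1 and was at least 2.52-fold higher, Col4a1, a basement membrane collagen, rose by 0.67 (SE 0.12, not called with line means as the replicates, adjusted p = 0.0703), and Apoe fell by 0.60 (SE 0.10). In the mesoderm list 3 of 8 rose and 0 fell (adjusted p = 0.264), led by Bmp4 (1.53, SE 0.10), and 5 members were not called. In the neural list 2 of 6 rose and 2 fell (adjusted p = 0.432). In trophectoderm 5 of 10 rose and 2 fell (adjusted p = 0.534), with Igf2, a growth factor, at 0.77 (SE 0.10) and Phlda2 at 0.71 (SE 0.12). In the germline list 2 of 11 rose and 7 fell (adjusted p = 0.179), and Kit, the receptor of stem cell factor, fell by 1.02 (SE 0.10). Except for the pluripotency, p53 and stress lists, the counts adjusted over the list alone were the same as those over all features in this comparison.

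Imprinted genes changed both ways. Of 25 tested 7 rose and 7 fell (median 0.08, mean -0.04, camera direction up, adjusted p = 0.947). Cdkn1c, a cyclin-dependent kinase inhibitor expressed from the maternal copy, rose by 1.89 (SE 0.10), while Grb10, a growth-factor receptor adaptor, fell by 2.01 (SE 0.09) and Mkrn3 by 1.22 (SE 0.11). Peg3, a paternally expressed zinc-finger gene, was not detected in the iPS lines and was at least 2.08-fold lower (adjusted p = 5.49e-07). Dlk1 differed by 0.22 (SE 0.09, adjusted p = 0.0452), and this call was lost under most alternatives, among them leaving out any 1 array other than KU-iN3 replicate 1 (adjusted p = 0.0517 to 0.294). Meg3, H19 and Ddx3y were not analysed here. Neither Xist, the silencer of the inactive X chromosome, nor the Y-linked Eif2s3y was detected on any array. J1 is a male line, so the missing Eif2s3y signal does not tell the sex of the iPS lines. In the list of X-inactivation and Y-linked genes only Tsix, the antisense partner of Xist, passed the detection filter. It was not detected in J1 and was at least 1.08-fold higher (adjusted p = 0.0254). Its log2 difference of 0.28 was 0.21 and 0.34 without J1 replicates 1 and 2, and the call was lost in both cases. With line means as the replicates it was not called either (adjusted p = 0.281). By line, Tsix was called higher in KU-iN1 (0.46) and KU-iN2 (0.36) but not in KU-iN3 (0.02). Of the 24 genes of the 2-cell-like list 14 are on the array, and none of these passed the filter.

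None of the cell cycle, chromatin and signalling lists was called, and all but the WNT targets had members called on both sides. In the proliferation list 8 of 25 rose and 5 fell (adjusted p = 0.658): the D-type cyclins Ccnd3 and Ccnd1 rose by 1.42 (SE 0.14) and 1.20 (SE 0.11), and the mitotic kinase Cdk1 and the topoisomerase Top2a fell by 1.37 (SE 0.12) and 0.85 (SE 0.10). In the DNA methylation and chromatin list 5 of 21 rose and 7 fell (adjusted p = 0.534). Tet1, a 5-methylcytosine dioxygenase, fell by 2.08 (SE 0.15), the demethylase Kdm5b by 0.98 (SE 0.10) and the Polycomb methyltransferase Ezh2 by 0.92 (SE 0.11). In the LIF and BMP target list 4 of 12 rose and 3 fell (adjusted p = 0.827; median -0.08, mean 0.23, camera direction up), with the BMP targets Id1 and Id3 at 1.91 (SE 0.14) and 1.19 (SE 0.12). In the WNT target list 3 of 4 rose and 0 fell (adjusted p = 0.126), Notum, a secreted WNT inhibitor, by 0.62 (SE 0.11), though its other probe had the opposite sign. Among Nodal-activin targets 3 of 6 rose and 1 fell (adjusted p = 0.311), Gdf3 by 0.78 (SE 0.10) beside both Lefty genes. In the p53 list 7 of 18 rose and 7 fell (7 and 8 adjusted over the list alone; adjusted p = 0.919), with the nuclease Aen at 0.77 (SE 0.09) and Ccng1 at -0.63 (SE 0.08).

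Lists of metabolism, the interferon response, stress and control genes were not called either. In the glycolysis and hypoxia list 5 of 26 rose and 12 fell (adjusted p = 0.0926). Vegfa, the endothelial growth factor, fell by 1.93 (SE 0.10), the aldolase Aldoc by 1.10 (SE 0.09) and the hexokinase Hk1 by 0.80 (SE 0.09), and Ddit4, an inhibitor of mTORC1, was not detected in the iPS lines and was at least 2.32-fold lower. Among oxidative phosphorylation genes 11 of 30 rose and 6 fell (adjusted p = 0.534), Atp5j by 1.02 (SE 0.11) and Cycs, cytochrome c, by 0.57 (SE 0.10). In cholesterol synthesis 9 of 17 rose and 2 fell (adjusted p = 0.264), with Mvd at 1.11 (SE 0.11) and Fdps at 0.94 (SE 0.10). In the interferon list 7 of 10 rose and 1 fell (adjusted p = 0.0797): the antiviral membrane protein Ifitm3 rose by 1.48 (SE 0.13) and Oas1g by 1.15 (SE 0.11), and Bst2 fell by 1.12 (SE 0.12). In the immediate early and stress list 8 of 18 rose and 6 fell (9 and 6 adjusted over the list alone; adjusted p = 0.924; median 0.22, mean -0.17, camera direction up). Against the rises of Egr1 and Fos, the stress-response genes Chac1, Ddit3 and Trib3 changed by -4.74 (SE 0.16), -2.91 (SE 0.11) and -2.26 (SE 0.10). Of 12 housekeeping controls 5 rose and 1 fell (adjusted p = 0.264), B2m by 0.86 (SE 0.12) and Rpl13a by 0.68 (SE 0.11). Actb, the gene of beta-actin, was higher by 0.49 (SE 0.10) on its brightest probe, but the mean of its probes gave -0.44, and with line means as the replicates it was not called (adjusted p = 0.0614).

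Each line compared with J1 gave similar genes. Trh rose by 3.58 (SE 0.13) in KU-iN1, 3.55 (SE 0.12) in KU-iN2 and 3.51 (SE 0.12) in KU-iN3, Gsta3 by 3.51 (SE 0.13), 3.27 (SE 0.12) and 3.22 (SE 0.12), and Fmr1nb was at least 5.18-fold, 7.42-fold and 5.34-fold higher. Lefty2 rose by 3.44 (SE 0.12) in KU-iN1 and 3.62 (SE 0.11) in KU-iN2, and Egr1 by 3.30 (SE 0.11) in KU-iN2 and 3.28 (SE 0.11) in KU-iN3. H4c18 fell by 6.80 (SE 0.13), 6.49 (SE 0.12) and 6.78 (SE 0.12). The limma fit called 4834 features in KU-iN1 (2417 higher, 2417 lower), 5218 in KU-iN2 (2644 higher, 2574 lower) and 5394 in KU-iN3 (2856 higher, 2538 lower). Of these 813, 798 and 853 differed at least 2-fold.

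The same 3652 features were called in the same direction in all 3 lines against J1, 1839 higher and 1813 lower. Independent lists of these sizes would share 330 (177 higher, 153 lower). The 3 comparisons share the J1 arrays and so are not independent, and an excess over 330 alone does not show a shared change. Simulated unchanged lines, set against simulated J1 arrays that they shared, had at most 3 calls by limma in any one line, too few for their shared count to serve as a comparison. Another 20 features were called in opposite directions in some pair of lines. The fold changes of the lines correlated at a mean r of 0.936 across genes, against 0.565 in the simulation, with a covariance of 0.377 against 0.0106.

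Fibroblast and feeder markers were called higher by camera in each line. In KU-iN1 8 rose and 1 fell (adjusted p = 0.0351, and adjusted p = 0.336 with an estimated correlation), in KU-iN2 8 rose and 1 fell (adjusted p = 0.0282, and 0.386 with an estimated correlation) and in KU-iN3 9 rose and 0 fell (adjusted p = 0.0186, and 0.521 with an estimated correlation). In KU-iN2 median centring gave an adjusted p of 0.0668 for it and the mean of a gene's probes 0.0519. Glycolysis and hypoxia genes were called lower in KU-iN1, where 1 rose and 14 fell (2 and 14 adjusted over the list alone; adjusted p = 0.0130, and 0.188 with an estimated correlation). They were also called lower in KU-iN2, where 2 rose and 14 fell (adjusted p = 0.0282, and 0.386 with an estimated correlation), but not without J1 replicate 2 (adjusted p = 0.0957). Interferon response genes were called higher in KU-iN2, where 6 rose and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 0.0282, and 0.446 with an estimated correlation), but not without J1 replicate 1 (adjusted p = 0.0614).

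Few genes were called between KU-iN1 and KU-iN2. The limma fit called 2 genes, with 1470 of 10159 features at an unadjusted p under 0.05. The count was 42 without KU-iN1 replicate 2, 6 without either J1 array, 0 by limma without KU-iN1 replicate 1 or KU-iN2 replicate 1 (1087 and 1367 at an unadjusted p under 0.05), and 1 without any other array. Actg1, the gene of gamma-actin, was not detected in KU-iN2 and was at least 1.39-fold higher in KU-iN1 (adjusted p = 0.00692), and Tgm1, a transglutaminase, was higher by 0.72 (SE 0.11, adjusted p = 0.0372). The call of Actg1 was lost without KU-iN1 replicate 1 (adjusted p = 0.0574) or KU-iN2 replicate 1 (adjusted p = 0.0519), and that of Tgm1 without any 1 array of KU-iN2 or KU-iN3 or without KU-iN1 replicate 1 (adjusted p = 0.0746 to 0.225). Both calls were also lost with median centring and with array weights (adjusted p = 0.0596 to 0.271). Camera called 0 of 22 lists, with 3 at an unadjusted p under 0.05.

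KU-iN1 had lower signal than KU-iN3 for genes of glycolysis. Of 26 members tested 8 fell and 0 rose (14 and 0 adjusted over the list alone), among them the phosphofructokinase genes Pfkl (-0.97, SE 0.11), Pfkp (-0.78) and Pfkm (-0.52). Camera gave an adjusted p of 4.61e-09, and the call held with an estimated correlation (adjusted p = 0.00856), as no other call among the 24 lists fixed beforehand did in any comparison. Endoderm markers were also lower, with 3 of 13 members down and 0 up (7 and 1 adjusted over the list alone; camera adjusted p = 0.00804): Dab2, an endocytic adaptor of visceral endoderm, and the collagen genes Col4a2 and Col4a1, at -0.99, -0.73 and -0.71. That call was lost with an estimated correlation (adjusted p = 0.220) and without KU-iN1 replicate 1 (adjusted p = 0.0771). Krt17, a keratin, rose by 0.81 (SE 0.11, adjusted p = 0.00150) and Ccnd2, a D-type cyclin, by 0.88 (SE 0.13, adjusted p = 0.00343). Aire, the autoimmune regulator, and Gpat2, an acyltransferase, were not detected in KU-iN1 and were at least 2.32-fold and 1.68-fold lower (adjusted p = 2.67e-05 for both). Zfpm1, a co-factor of GATA factors, fell by 1.09 (SE 0.14), Pramel12 fell by 1.07 (SE 0.13) and Aurkc, an Aurora kinase, by 1.05 (SE 0.13).

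In all 342 features were called between KU-iN1 and KU-iN3, 78 higher and 264 lower in KU-iN1, 9 of them at least 2-fold. The count fell to 95, 138 and 215 without KU-iN3 replicates 2, 3 and 1, to 131 and 173 without KU-iN1 replicates 1 and 2, and to 218 without KU-iN2 replicate 3. With median centring it was 37, and with a fit of only these groups 108.

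KU-iN2 and KU-iN3 differed most among the lines by this count. Glycolysis and hypoxia genes were lower in KU-iN2, where 12 of 26 fell and 1 rose (13 and 1 adjusted over the list alone; camera adjusted p = 0.00104, and adjusted p = 0.0856 with an estimated correlation), with Hk1 at -0.89 (SE 0.09) and Pfkl at -0.90 (SE 0.10). Oxidative phosphorylation genes were higher, where 7 of 30 rose and 0 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.00736, and adjusted p = 0.719 with an estimated correlation), with Ndufv2, a subunit of complex I, at 0.65 (SE 0.10). Rpl22l1, a ribosomal protein paralogue, rose by 1.25 (SE 0.20, adjusted p = 0.00170), S100a10 by 1.12 (SE 0.12) and Mad2l1, a spindle checkpoint protein, by 0.99 (SE 0.14). Aire fell by 1.29 (SE 0.10, adjusted p = 2.54e-05), Dnmt3l, a co-factor of the DNA methyltransferases, by 1.02 (SE 0.10), Fzd5, a WNT receptor, by 0.94 (SE 0.12) and Rfx2 by 0.93 (SE 0.10). Lefty2 was higher by 0.72 (SE 0.10) and Klf4 by 0.56 (SE 0.12), and Col4a2 lower by 0.90 (SE 0.11). Of the 2 other probes of Klf4 only 1 had the same sign, and with the mean of its probes the call was lost (0.19, adjusted p = 0.231).

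The limma fit called 1856 features between KU-iN2 and KU-iN3, 761 higher and 1095 lower in KU-iN2, and 8 of them differed at least 2-fold. With median centring 815 were called and the balance turned, to 547 higher and 268 lower. Without KU-iN3 replicates 2 and 3 the counts were 904 and 982, and without KU-iN2 replicates 2 and 3 they were 1097 and 1117.

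**Figure D3:**
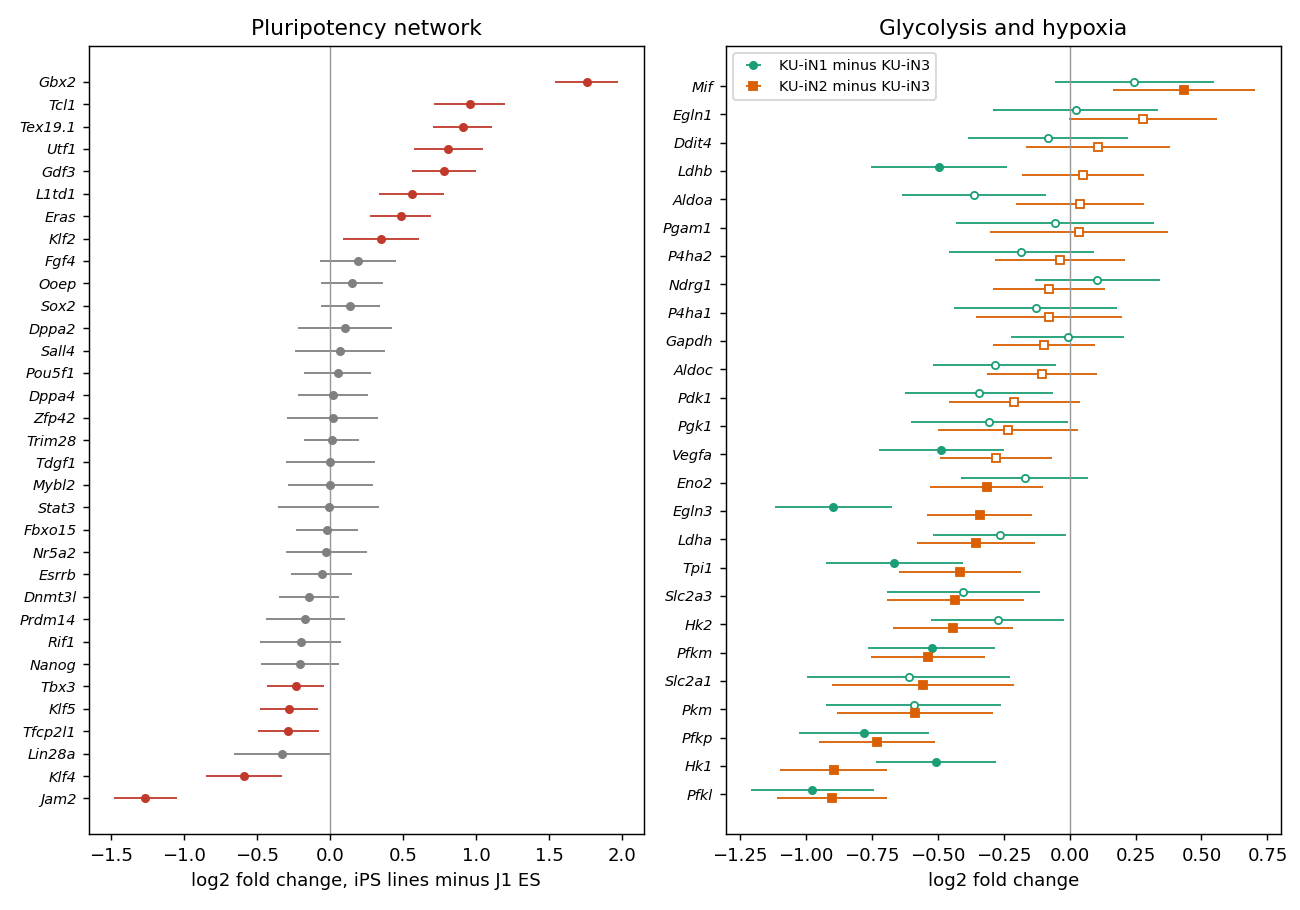
Log2 differences with 95% confidence intervals, for the 33 pluripotency network genes in the iPS lines minus J1 (left, adjusted p under 0.05 in red) and for the 26 glycolysis and hypoxia genes in KU-iN1 and KU-iN2 minus KU-iN3 (right, adjusted p under 0.05 filled). Of the called genes, 8 lie above and 5 below 0 on the left. On the right 8 were called lower and 0 higher in KU-iN1, and 12 lower and 1 higher in KU-iN2.

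Genes of 3 chromosomes were shifted as a group in the iPS lines against J1, a comparison chosen after the data were seen. The median log2 difference was 0.28 over 409 features of chromosome 1, 0.32 over 449 of chromosome 8 and 0.33 over 288 of chromosome 14, with 73.1%, 77.5% and 78.1% of them above 0. Camera over 20 chromosomes gave adjusted p of 1.36e-05, 5.59e-07 and 2.73e-08, and with an estimated correlation adjusted p of 0.00918, 0.000322 and 0.000783. No other chromosome was called in this comparison. The medians were 0.27, 0.31 and 0.30 on chromosome 1 in KU-iN1, KU-iN2 and KU-iN3, 0.34, 0.32 and 0.28 on chromosome 8, and 0.30, 0.35 and 0.34 on chromosome 14. Without these chromosomes camera called 2 gene lists in the iPS lines against J1 in place of 1.

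**Figure D4:**
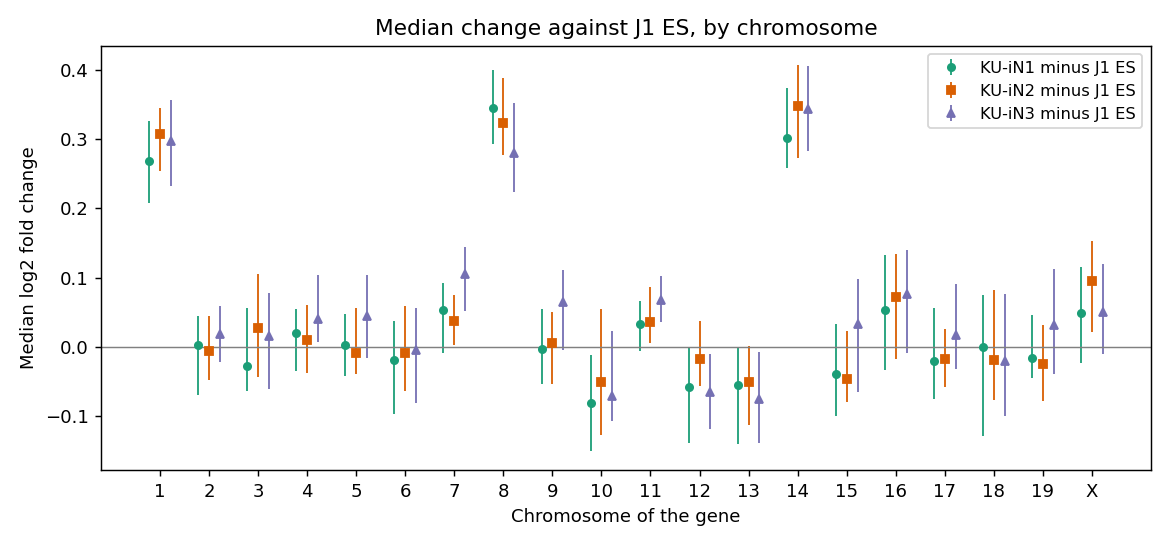
Median log2 difference of each line minus J1 over the genes of each chromosome, with 95% bootstrap intervals over genes. Chromosomes 1, 8 and 14 lie at 0.27 to 0.35 in the 3 lines, above the other chromosomes.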

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

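The search for genes with opposite directions and the weighing of the difference between KU-iN2 and KU-iN3 were chosen only after the results of the comparisons were seen. Against J1, 18 named genes were called higher in 1 line and lower in another, with the difference between those lines called as well. The 3 comparisons share the J1 arrays, so a J1 value between those of the lines is enough to give this. Of the named genes, Pfkl, the liver-type phosphofructokinase, was lower than J1 in KU-iN1 and KU-iN2 (-0.50 and -0.43) and higher in KU-iN3 (0.47), with line differences of -0.97 (adjusted p = 0.000467) and -0.90 (adjusted p = 0.000164). Dnmt3l was lower in KU-iN1 and KU-iN2 (both -0.48) and higher in KU-iN3 (0.53), with a difference of -1.02 for each pair. Zfpm1 differed by -1.09 between KU-iN1 (-0.44 against J1) and KU-iN3 (0.65). Trim28, a co-repressor that silences retroelements, was -0.37 in KU-iN2 and 0.41 in KU-iN3 (difference -0.79), and its line difference was not called under 1 alternative, median centring (-0.43, adjusted p = 0.0503). Dcaf13 was 0.42 in KU-iN2 and -0.55 in KU-iN3 (difference 0.97).

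The 1856 features called between KU-iN2 and KU-iN3 contrast with 8 of them at least 2-fold, so most of these differences are small. A technical axis that also varies between replicates may account for part of them, and the differences between lines would then follow those between replicates across genes, where r was -0.119 with the replicates of KU-iN1 and 0.0695 with those of J1, and Spearman's correlation of the line difference with genomic length was -0.231, which leaves a difference in RNA quality open. Both r are under the size of 0.3 set beforehand as a sign of such an axis, but the one for KU-iN1 is over the 0.1 set to argue against it, so such an axis and a difference between the lines cannot be told apart. The 6 arrays allow only 10 splits into 3 and 3, too few for a share under 0.05: 1 of the 10, the real one, gave 1856 features, and the highest of the others gave 0. Every other split mixes arrays of the 2 lines, so any difference that follows the lines adds to the spread. Low counts there were likely in advance, and no conclusion is drawn from them. Which chip or day held each array is not given in the sources used here, so a batch that follows the lines cannot be told apart from a difference between the lines, which stays open as the biological explanation.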

How the results depend on the processing

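The alternatives with neqc, quantile normalization within probe blocks, and without chromosomes 1, 8 and 14 were chosen only after the data were seen; for every change given here the cause was not tested, except that stricter thresholds call fewer genes by construction. Over all alternatives, 4352 values of named genes kept their direction and side of the threshold, 147 lost the call and 11 reversed. For gene lists 247 kept both and 17 lost the call, and for counts and array correlations 202 stayed within 1.5 times, 57 moved and 2 lost the call. Reversed for Pou5f1 were -0.0227 with cyclic loess, -0.10 with the mean of probes, -0.0121 within probe blocks and -0.00760 without J1 replicate 2 (leaving out 1 array at a time gave up to 0.117). Reversed for Zfp42 were -0.0530 with cyclic loess, -0.0383 within probe blocks, -0.0106 without KU-iN3 replicate 2, -0.0405 without KU-iN1 replicate 1, -0.0365 without KU-iN2 replicate 1 and -0.0686 without J1 replicate 1 (leaving out 1 array gave up to 0.104). Actb was -0.44 with the mean of probes. None of these Pou5f1 and Zfp42 values was called in the setting reported. At 2-fold or more, the counts for the iPS lines, KU-iN1, KU-iN2 and KU-iN3 against J1 were 742, 813, 798 and 853, with 524 shared, and between lines 1 (KU-iN1 and KU-iN2), 9 (KU-iN1 and KU-iN3) and 8 (KU-iN2 and KU-iN3). Line means as replicates gave 3491 for the iPS lines. For KU-iN1 against KU-iN2 the count of 2 became 4 with no background correction, the series matrix, neqc and probe blocks, and 0 (limma) with median centring and array weights, where 1065 and 1237 had an unadjusted p under 0.05. It became 1 with no detection filter, detection on all 10 arrays, each probe on its own, without the 3 chromosomes, with only the groups compared and at an adjusted p under 0.01. For KU-iN1 against KU-iN3 the count of 342 became 37 with median centring, 142 with no detection filter, 195 with array weights, 108 with only the groups compared and 76 at an adjusted p under 0.01. For KU-iN2 against KU-iN3 the count of 1856 became 815, 2889 and 672 with median centring, array weights and an adjusted p under 0.01. The 1 list called for the iPS lines became 0 with median centring and with an estimated correlation, 5 with no detection filter, 3 with each probe on its own, and 2 within probe blocks and without the 3 chromosomes.

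Leaving out 1 array at a time gave 4513 to 5863 for the iPS lines against J1, 3878 to 4860, 4175 to 5400 and 4316 to 5579 for KU-iN1, KU-iN2 and KU-iN3, 2833 to 3524 shared, 1 list each time, and -0.0550 to -0.0530 for the difference of array correlations. Between lines it gave 0 to 42 for KU-iN1 and KU-iN2 (0 by limma without KU-iN1 replicate 1 or KU-iN2 replicate 1, with 1087 and 1367 at an unadjusted p under 0.05, 42 without KU-iN1 replicate 2, 6 without either J1 array, and 1 without any other array), 95 to 318 for KU-iN1 and KU-iN3 and 904 to 2085 for KU-iN2 and KU-iN3. A group left with 1 array is assumed to vary like the others. Without J1 replicate 1 or 2 the exact permutation p of the correlation difference is 0.111, the smallest that design allows. The replicate numbers do not pair the samples: deviations of same-numbered arrays correlated at -0.422 to 0.261 over 13 pairs, 2 of them over 0.1, and 2 of 10 arrays correlated best with their own number. With the replicate block the counts were 5377, 4469, 4713 and 4811 against J1, 0 (1216 at an unadjusted p under 0.05), 75 and 1366 between lines, and 3215 shared, with 1 list called. The chip block was not run, since no chip is given. Most probes lie near the receptor probes, so small changes of dim genes are outside what these arrays can measure.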

Other observations

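The lists of ATF4 targets, replication-dependent histones and chromosomes, and all of their tests, were chosen only after these patterns had been seen in the data. Genes driven by ATF4, the transcription factor of the amino acid and endoplasmic reticulum stress response, were lower in the iPS lines than in J1. Nupr1 fell by 4.78 (SE 0.13), the amino acid transporter Slc1a4 by 2.28 (SE 0.13), the cysteinyl-tRNA synthetase Cars by 2.02 (SE 0.13), the mitochondrial folate enzyme Mthfd2 by 1.27 (SE 0.09) and the asparagine synthetase Asns by 0.78 (SE 0.13). Of 31 targets tested 25 fell and 1 rose (median -1.08, camera adjusted p = 1.63e-12, and adjusted p = 0.00485 with an estimated correlation). Chac1, Ddit3, Trib3 and Nupr1 had prompted the list. Without them 21 of 27 fell and 1 rose (median -0.86, camera adjusted p = 1.40e-09, and adjusted p = 0.00563 with an estimated correlation). The 27 still hold Atf4 (-0.67) and Asns, which were on the stress list tested earlier, so the reduced list is not clear of genes already seen. Between the lines 0 targets were called for KU-iN1 against KU-iN2 or KU-iN3 and 3 fell in KU-iN2 against KU-iN3.

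Replication-dependent histone genes, whose transcripts end in a stem-loop in place of a poly(A) tail, were the largest falls: of 50 tested 37 fell and 0 rose (median -3.09), with array medians of 9.22 to 9.57 in the iPS lines and 13.6 and 13.3 in J1, and they were 33 of the 52 named genes that fell at least 4-fold. A larger share of J1 cells in S phase is argued against by the S-phase genes (median 0.241), and the normalization between arrays by the histone median of -2.90 or lower under every normalization run and with none. Better labelling of RNA without a poly(A) tail in the J1 samples stays open as a candidate explanation: 4 other such RNAs had a median of 0.118, which meets the bound set beforehand to argue against it (above -0.5 with at least 3 genes), but after the value was seen that bound was judged too weak, since 4 genes are few, snoRNA probes can read host transcripts and Neat1 has a form with a tail. Of the 13 histone genes not called, 10 are H2A genes at 14.63 to 16.02 in J1 that differed by -0.24 to 0.18. The rest are H1f2, detected on all 10 arrays at 10.16 in J1 (difference 0.19), and the dim H2bc8 and H2bc18, at 7.48 and 7.70 in J1. H2ac10 read 16.02 on both J1 arrays (SD 0), as high as the highest value of a Gapdh probe. Most of the other H2A genes not called were almost as high in both groups. The iPS means were 15.92 for H2ac10 and 15.56 for H2ac20. Near a ceiling neither a rise in J1 nor a lower level in the iPS lines need show. Whether the raw intensity of these probes was saturated was not tested, so those genes do not decide on better labelling. H2ac12, H2ac15 and H2ac22 lay lower, at 14.63 to 14.97 in J1, and differed by 0.08, -0.10 and 0.18. Better labelling in J1 alone would not give this if the probes of H2ac12, H2ac15 and H2ac22 read only RNA without a tail. Whether the H2A probes read near-identical copies with a tail was not tested, so these genes do not decide on better labelling. J1 may also hold more of the histone transcripts that fell, or carry tails on them, which was not tested, and a labelling or handling batch that coincides with J1 cannot be told apart from the line.

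The higher signal of genes on chromosomes 1, 8 and 14 in the iPS lines may reflect an extra copy in those lines or a missing one in J1, which would move most genes of a chromosome. At least 73.1% of the genes of each were above 0, and the medians were lowest, at 0.20 to 0.21, for genes with a mean log2 value under 9, against 0.28, 0.38 and 0.52 from 9 to 11 and 0.41, 0.47 and 0.40 above. Local regions such as strain variants are argued against by the lowest median of 12 segments in gene order, 0.190, and a trend with signal level, gene length or probe block by the 89.1% or more of each shift that stayed after a fit of all of these. The normalization between arrays is argued against by a shift of 0.211 or more under every normalization run and with none. If signal followed copy number in full, 1 copy in J1 against 2 in the lines would give a 2-fold difference. All the medians given above were smaller, also those of the brighter genes. How fully signal follows copy number on these arrays was not tested, so the size does not choose between an extra and a missing copy. The data do not tell which side carries the difference, whether all cells of a line do, or how 3 separately picked colonies came to share it, and no chromosome count was analysed here.

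The dimmer probes of Actb were uneven between replicates. On all 4 dimmer probes KU-iN1 replicate 1 read higher than replicate 2, from 12.2 against 11.8 to 10.3 against 8.01, while the brightest probe read 14.9 and 14.8. The dimmest read 9.29, 9.92 and 8.52 in KU-iN2, 8.93 to 9.14 in KU-iN3, and 10.5 and 10.2 in J1. On that probe the unevenness therefore also lies between J1 and most iPS arrays. Another of the 4 read 12.1 and 11.8 in J1, within the range of the iPS arrays.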
